A study of Homo sapiens with 11 samples.

How the data were processed

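RNA from 11 samples of 786-0 cells was analysed, 6 kept in DMSO vehicle (control) and 5 given everolimus in DMSO, all for 4 h. Per the labels' protocols, the cells were grown in DMEM, RNA was extracted with a Qiagen RNeasy kit and libraries were made with a TruSeq stranded mRNA kit, which selects polyadenylated RNA. The labels write the dose as "10um", which is read here as 10 µM. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

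The authors' table holds 20500 entries and 1 column per sample, and 0 of its columns were left unused. Its values are a signal that the authors deposited already scaled. The deposited values are never negative, and in every column the upper quartile (percentile 75) of the values above 0 lay between 999.57 and 1001.05, so each column had been scaled to about 1000. The submitters' processing notes name the genome build hg19, Picard 1.64, SAMtools and RSEM, a program that estimates read counts per gene and shares ambiguous reads between genes. They give those names without roles. The aligner, the gene annotation, the use of strand in counting and the reason for the scaling are not given in the sources used here. From the values alone, a column behaved as estimated read counts times a constant. Low values lay on multiples of a step that was the same for all genes of a column, and 89.4% to 94.0% of the values up to 200 reads were whole multiples of it within 0.1 reads. The step, the value of 1 read, was 0.307 to 1.05 units. Dividing by it gave 14230238 to 36827127 estimated reads per library in the controls and 29760566 to 52521727 with everolimus. A count of 3 reads corresponded to 0.92 to 3.15 units, and this floor covers counting error only. Because a part of the values was fractional, the reads were not treated as recovered counts and no count model was used.

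Genes are named as in the table. Of its names, 17266 matched a current symbol in a RefSeq gene table for a later assembly (GRCh38.p14), 2610 matched only an older symbol and 598 matched none. That table was used for names alone and no coordinates are given. There were 26 entries named by whole numbers of the kind a spreadsheet makes from date-like symbols. Of these, 19 reached the filter and were tested, and no gene name was assigned to any. SLC35E2 stood on 2 lines, which were kept apart. Values of 0 in every library were found for 3397 entries. Reads from near-identical genes and pseudogenes can be divided differently between libraries by the estimation, so levels of such genes are uncertain.

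The test was limma 3.58.1 in R 4.3.3 with an intensity trend, on log2(value + 1), without further scaling, over the 12668 genes with a value of at least 10 in at least 5 samples. P-values are two-sided and were adjusted by Benjamini and Hochberg over all tested genes, with a threshold of 0.05. A fold change is on the log2(value + 1) scale and understates the change of low genes. Errors of levels are SD over samples and errors of log2 fold changes are standard errors. Gene lists were tested with camera in limma with a preset correlation between genes of 0.01, adjusted over the 28 lists with at least 5 tested members out of 30, and camera with an estimated correlation was computed beside it. Members past the threshold were counted after adjustment over all genes and after adjustment over the list alone. The groups, the test, the 30 gene lists, the rule for named genes and a set of alternatives were fixed before the data were examined. That rule took the 6 largest rises and 6 largest falls among genes past the threshold with a mean log2 value of at least the median of the tested genes (8.98) and no overlap between groups. To these it added, for the 10 called lists with the smallest p, the 2 members with the smallest p in the list's direction. It further took the member with the smallest p of every other list that had a member past the threshold, and MTOR and FKBP1A. It named 50 genes, and some of them are not reported here. Other genes named as list members or as largest changes were chosen after their values were seen.

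The share of whole low values divided the libraries at its largest gap into a first set (controls 1 to 3, everolimus 1 and 2; 89.4% to 90.3%) and a second set (controls 4 to 6, everolimus 3 to 5; 93.4% to 94.0%). The labels name no batch. Everolimus was compared with control within each set and with the set as a covariate. Medians of lists within a set are over the members kept by the filter over all 11 libraries, unless the filter within that set is named. That filter needs a value of at least 10 in at least 5 libraries of the set, so it drops genes that are low in the controls. Other alternatives were centring on the median log ratio, quantile normalization, no filter and a stricter filter on low values, pseudocounts of 0.1 and 10, limma without trend, sample weights, the replicate number as a block, each sample left out, reads thinned to the total of the shallowest library and scaled again to an upper quartile of 1000, voom weights on the estimated reads, and an exact permutation test of each list's mean over all 462 splits of the samples. GC content and transcript length came from GENCODE release 29 transcripts for 96.7% of the tested genes.

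The test was tested on 10 simulated data sets for this comparison, with 12649 genes tested. Mean levels came from the control samples, but a fixed spread was assumed for all genes, without a difference between library sets. The rates that follow hold for that assumed spread and not for the spread of the real samples. It recovered 48.0% of genes changed 1.25-fold, 96.6% of those changed 1.5-fold, 99.0% of those changed 2-fold and 100.0% of those changed 4-fold, and 6.5% of the calls were unchanged genes. In a further simulated data set with no gene changed, limma made 0 calls. Lists were tested in the first of the 10 data sets only, where 0 of 30 simulated lists of unchanged genes were called. The simulated genes were drawn independently, so this could not test lists whose members vary together. Members of real lists did so, with an estimated correlation of 0.537 for cytosolic ribosomal proteins. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for reading the table and drawing.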

Results

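The series measured gene expression in 786-0 cells, a line of human clear cell renal carcinoma that lacks functional VHL, after 4 h with everolimus or with DMSO vehicle. Everolimus, a derivative of rapamycin, binds the product of FKBP1A and inhibits the kinase mTOR in its complex 1, which drives protein, lipid and nucleotide synthesis. The comparison shows which transcripts differ after 4 h with everolimus, and these values do not measure mTOR activity. There were 6 control and 5 everolimus samples, with 14230238 to 36827127 estimated reads per control library and 29760566 to 52521727 per everolimus library. Levels are given in scaled estimated read counts (units), where the upper quartile of the genes with a value above 0 was set to 1000 in each library and 1 read was worth 0.307 to 1.05 units. The renal markers PAX8 (3189 ± 78.7 units, SD, n = 6) and MET (10862 ± 621) were high in the controls, while CA9 stood at 1.41 ± 1.24.

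Within 4 h, everolimus was followed by a large rise of cytokine and NF-kappaB target transcripts, smaller rises of genes induced by ERK and YAP signalling, and falls of cholesterol, fatty acid and mitotic genes. Only the NF-kappaB and cytokine list kept its call in camera with an estimated correlation between genes, and the other lists named here did not (adjusted p = 0.161 to 0.170). Of 12668 genes tested, 6997 changed, 3528 upward and 3469 downward, and 1500 of them changed at least 1.5-fold. IL8 (now CXCL8, a neutrophil chemokine) rose 255-fold, from 29.5 ± 5.86 units (SD, n = 6) to 7687 ± 596 (n = 5). ACACA, acetyl-CoA carboxylase of fatty acid synthesis, fell by 0.89 on the log2 scale (SE 0.034), from 2842 ± 101 to 1538 ± 53.2 units. Within the first library set 5388 genes changed and within the second 5410, and the sets share no library. Of the genes called in the first set, 97.6% had the same sign of fold change in the second, and of those called in the second 97.4% had the same sign in the first. The genes called over all 11 libraries agreed in sign in 99.9% of cases, which the selection on both sets favours, and the 5671 uncalled genes in 61.0%. A limma test for a difference of the everolimus effect between the sets called 0 genes, with 783 at an unadjusted p under 0.05. The first principal component (58.4% of the variance) separated everolimus from control, and the next (22.2%) separated the library sets.

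**Figure D1:**
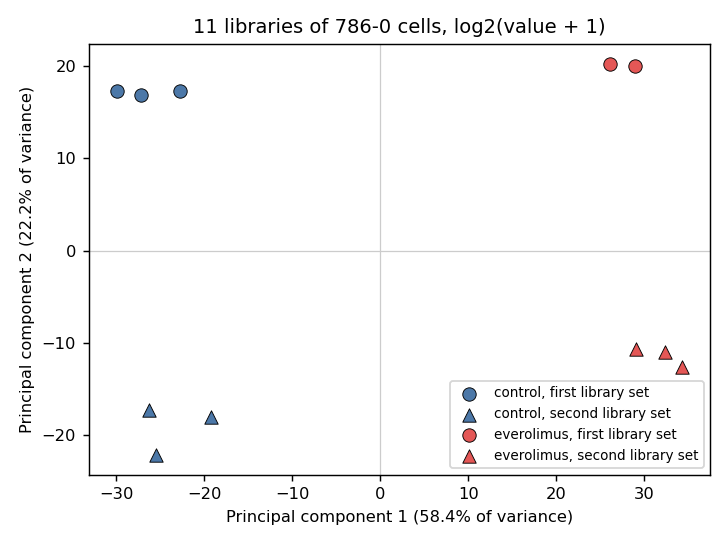
Principal components 1 (58.4% of variance) and 2 (22.2%) of log2(value + 1) over the tested genes, each point a library, coloured by treatment and shaped by library set. The 5 everolimus libraries lie to the right and the 6 controls to the left, and the sets separate along the vertical axis.

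**Figure D2:**
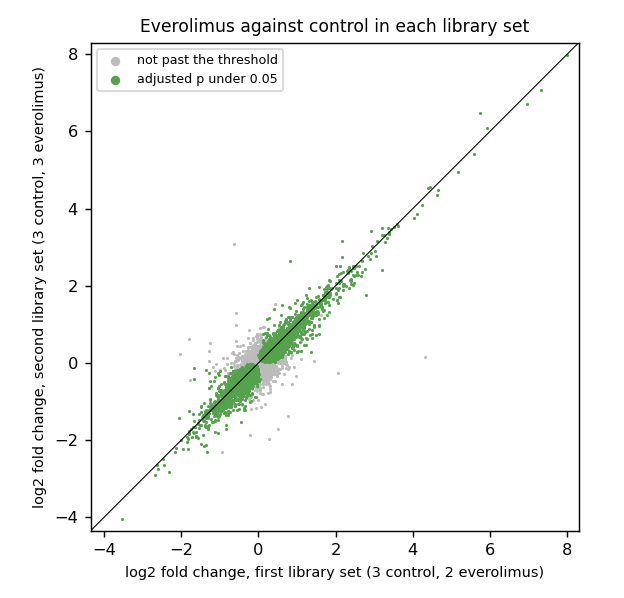
Log2 fold change of each tested gene, everolimus against control, in the first library set (horizontal) and the second (vertical), with genes past the threshold over all 11 libraries in green and the diagonal of equal change as a line. The Pearson correlation across genes was 0.92 and the Spearman correlation 0.85, over genes that are not independent of each other.

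Among well-expressed genes, the tight junction gene CLDN1 rose 10.5-fold (583 ± 104 to 6023 ± 138 units; log2 3.39, SE 0.097, limma adjusted p = 1.83e-12). INHBA, which encodes an activin subunit, rose by a log2 of 3.29 (SE 0.140), LAMB3, a laminin chain, 9.75-fold, and PLAU, the urokinase gene, by 2.80 (SE 0.054). IER3, an early response gene, rose by 2.56 (SE 0.067). The largest falls were those of CD24, a surface glycoprotein, from 31226 ± 4613 to 7958 ± 1392 units (log2 -1.98, SE 0.119, adjusted p = 4.23e-09), and of EGLN3, a HIF prolyl hydroxylase (log2 -1.91, SE 0.090). The epithelial transcription factor ELF3 (-1.79), the mTOR inhibitor gene DDIT4 (-1.77), MAP7D2 (-1.76) and SAMD11 (-1.76) followed. These genes moved the same way in each library set, CD24 by -1.86 and -2.06. CD24 has near-identical processed copies in the genome, so how its reads were divided is uncertain.

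The NF-kappaB and cytokine list showed the strongest change of any list. Of 19 members tested, 18 rose and 0 fell, over all genes and adjusted over the list alone, with a median log2 fold change of 2.47 (2.47 in the first set and 2.50 in the second). With the filter applied within each set, the medians were 2.05 over 14 members and 1.94 over 15. Besides IL8, the apoptosis inhibitor BIRC3 rose from 444 ± 21.7 to 2460 ± 87.0 units (log2 2.47, SE 0.040). IL6 rose from 18.0 ± 3.66 to 2148 ± 66.4 units, and the adhesion molecule ICAM1 from 1766 ± 109.6 to 9787 ± 180. NF-kappaB's own inhibitors NFKBIA (1.72) and TNFAIP3 (3.45) rose too, as did the subunits NFKB1 (1.07), NFKB2 (1.69) and RELB (1.92). NFKBIZ alone did not pass (-0.12, adjusted p = 0.305). The list's camera adjusted p was 1.07e-17, and 0.00239 with an estimated correlation.

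**Figure D3:**
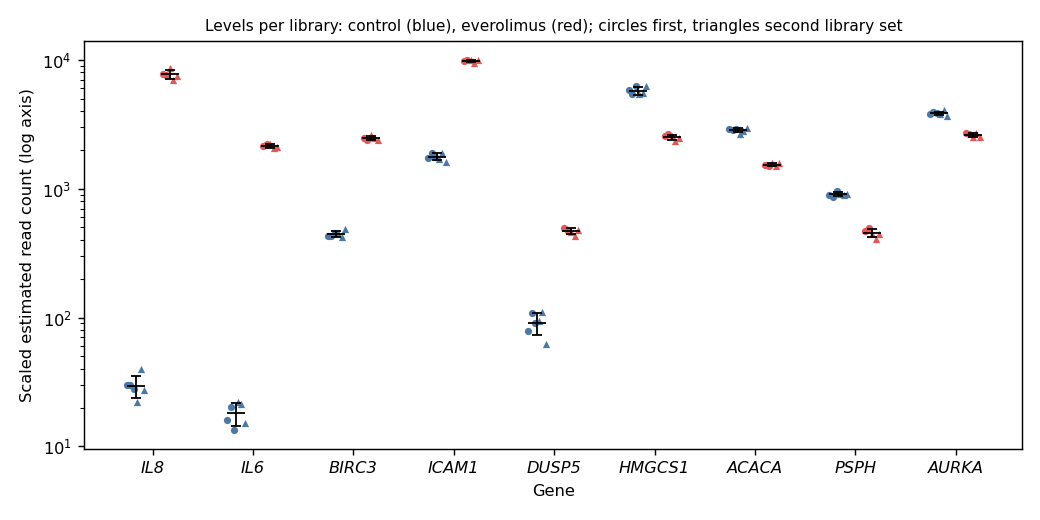
Scaled estimated read counts (log axis) of 9 genes in each of 6 control (blue) and 5 everolimus (red) libraries, circles for the first and triangles for the second library set, with mean and SD as bars. IL8 rose from 29.5 to 7687 units on average, and HMGCS1 fell from 5766 to 2512.

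Genes induced by ERK signalling, early response genes and YAP targets rose. Of 13 genes of the ERK pathway output, 12 rose and 1, the receptor EPHA4, fell (-1.17), with a median of 1.69 (1.73 and 1.65 in the sets). With the filter applied within each set, 10 members were tested, 9 of them higher, and the median was 1.18 in both sets. DUSP5, a phosphatase of ERK, rose from 90.7 ± 18.2 to 467.5 ± 24.5 units (log2 2.38, SE 0.121), and the transcription factor ETV5 from 190.8 ± 33.8 to 661.1 ± 23.6 (1.80, SE 0.096). Of 17 immediate early genes 13 rose, among them KLF6 (1.66), ATF3 (1.67) and IER3, while JUND (-0.44) and ZFP36 (-0.33) fell and EGR1 (-0.16, adjusted p = 0.458) and IER2 (0.11, adjusted p = 0.278) did not pass. The median was 0.64 (0.60 and 0.68). Of 12 YAP and TEAD targets 10 rose and 1, ARHGEF17, fell, with a median of 0.87 (0.86 and 0.88). NUAK2, a kinase, rose by 2.67 (SE 0.055), CTGF (now CCN2) by 2.12, and CYR61 (now CCN1), a matrix protein, from 5310 ± 254.6 to 13069 ± 151 units. The counts were the same adjusted over each list alone. Camera adjusted p-values were 3.08e-06, 1.29e-05 and 7.82e-06 in this order, and with an estimated correlation the calls were lost (adjusted p = 0.161, adjusted p = 0.161 and adjusted p = 0.170).

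Lipid synthesis genes fell together. Of 25 genes of cholesterol synthesis and uptake, 23 fell and 0 rose, with a median of -0.55 (-0.53 and -0.56 in the sets). HMGCS1, which makes the precursor of mevalonate, fell from 5766 ± 419.4 to 2512 ± 109.9 units (log2 -1.20, SE 0.049, adjusted p = 7.3e-11). IDI1 (-1.06) and SC4MOL (now MSMO1; -1.07) fell as well, whereas SREBF2, the transcription factor of the pathway (0.04, adjusted p = 0.303), and PMVK (-0.01, adjusted p = 0.885) did not pass. Of 17 genes of fatty acid synthesis 14 fell and 0 rose, with a median of -0.62 (-0.66 and -0.52). Besides ACACA, LPIN1 fell by a log2 of -1.16 (SE 0.051) and the transcription factor SREBF1 by -1.50 (SE 0.107). ACLY (0.04), GPAM (-0.01) and ME1 (-0.07) did not pass. Counts adjusted over each list alone were the same, 23 and 14. The camera adjusted p-values were 7.33e-12 and 8.82e-07, and with an estimated correlation both calls were lost (adjusted p = 0.161 for each).

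Mitotic genes fell by small amounts. Of 29 genes of G2/M and mitosis, 26 fell and 1, AURKB (0.19), rose, over all genes and adjusted over the list alone. The median was -0.31 (-0.32 and -0.33 in the sets). KIF20A, a kinesin of cytokinesis, fell from 3014 ± 73.1 to 2072 ± 58.1 units (-0.54, SE 0.030), and AURKA, a spindle kinase, from 3838 ± 127 to 2610 ± 84.4 (-0.56, SE 0.032). CDC20 (-0.52) and CCNB1 (-0.48) fell too. The camera adjusted p was 3.52e-09, and adjusted p = 0.161 with an estimated correlation. Genes of G1/S and DNA replication went both ways, with 10 of 27 higher and 6 lower (9 and 9 after thinning, 10 and 2 in the first set, 8 and 3 in the second), and the list was not called (camera adjusted p = 0.339). MCM7, a replicative helicase subunit, rose by 0.39 (SE 0.033), CCNE1 by 0.57 and E2F1 by 0.39.

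Of 31 targets of ATF4 and genes of amino acid supply, 18 fell and 6 rose, with a median of -0.19 (-0.19 and -0.20). PSPH, which makes serine, fell from 902.0 ± 31.7 to 452.3 ± 33.2 units (SE of the log2 fold change 0.049). The stress-induced genes DDIT4, CHAC1 (-1.06), SESN2 (-1.02) and TRIB3 (-0.97) fell, and the hormone gene STC2 (1.02) and the transporter SLC7A1 (0.39) rose. Of 20 cytosolic aminoacyl-tRNA synthetases 10 fell and 0 rose, with a median of -0.10 (-0.09 and -0.11), led by TARS (-0.49, SE 0.034) and AARS (-0.42, SE 0.029). The counts were the same adjusted over each list alone. Camera adjusted p-values were 0.0049 and 0.0105, and with an estimated correlation adjusted p = 0.253 and adjusted p = 0.502.

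Of 15 chaperones and related genes of the endoplasmic reticulum 14 rose and 0 fell, with a median of 0.22 (0.29 and 0.19). HERPUD1, of the degradation of misfolded proteins, rose from 1376 ± 57.7 to 2086 ± 40.5 units (0.60, SE 0.034), EDEM1, of the same process, by 0.35 (SE 0.029) and the chaperone HSPA5 by 0.32. Of 15 targets of NRF2, the regulator of antioxidant genes, 10 rose and 1, the transporter ABCC2 (-1.07), fell, with a median of 0.16 (0.23 and 0.13). TXNRD1, thioredoxin reductase, rose from 8904 ± 269 to 16693 ± 828 units (0.91, SE 0.036) and HMOX1 by 1.34. Counts adjusted over each list alone were the same. Camera adjusted p-values were 4.6e-05 and 0.0149, and with an estimated correlation adjusted p = 0.161 and adjusted p = 0.279. Of 75 nuclear genes of oxidative phosphorylation 17 fell and 1, CYC1 (0.15), rose, while adjusted over the list alone 7 fell and 1 rose. After quantile normalization 29 fell, after thinning 26, and in the first and second library set 5 and 28. UQCRFS1 fell by 0.35 on the log2 scale. That list's median was -0.08 but 0.00 in the first set and -0.14 in the second. Its call (camera adjusted p = 0.024) was lost with an estimated correlation (adjusted p = 0.824), within the first set (0.645), without control 3 (0.0548) and without everolimus 4 (0.150).

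**Figure D4:**
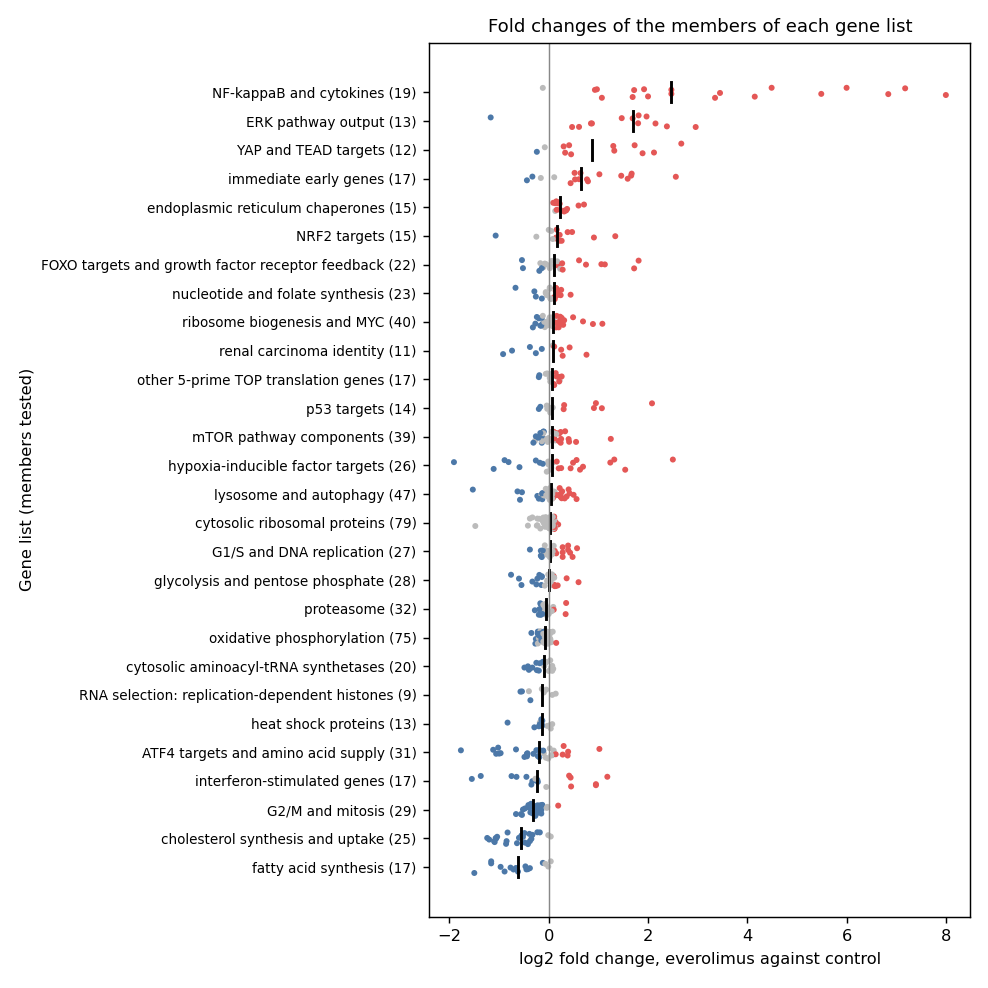
Log2 fold changes of the members of each of 28 gene lists, ordered by their median (black bar), with members past the threshold in red (higher) or blue (lower) and others in grey. The medians run from -0.62 for fatty acid synthesis to 2.47 for NF-kappaB and cytokines.

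Transcripts of the mTOR pathway itself shifted in both directions. Of 39 components 13 rose and 8 fell (9 and 10 after thinning, 12 and 10 after quantile normalization), and the list was not called (camera adjusted p = 0.263). The target MTOR was at 1909 ± 64.6 units in the controls and 1782 ± 56.9 with everolimus (-0.10, SE 0.033, adjusted p = 0.0215), a call lost without everolimus 2 (adjusted p = 0.0605) and within each set (0.0555 and 0.259). FKBP1A rose from 3270 ± 117 to 3849 ± 109 units (0.24, SE 0.033). SGK1, a kinase downstream of mTOR complex 2, rose from 242.2 ± 4.58 to 577.7 ± 29.8 (2.38-fold, SE of the log2 fold change 0.043), and RICTOR (0.41) and ULK1 (0.40) rose, while TSC1 fell (-0.26). Among 22 FOXO targets and receptor feedback genes, 9 rose, among them GADD45A (1.81, SE 0.062) and FOXO1 (1.72), and 4 fell, among them IRS2 (-0.54; camera adjusted p = 0.169). Of 47 genes of lysosome and autophagy 14 rose, MAP1LC3B by 0.40 (SE 0.033) and SQSTM1 by 0.42, and 9 fell, the regulators TFEB (-0.54) and PPARGC1A (-1.53) among them (camera adjusted p = 0.339). After thinning 13 of these genes rose and 14 fell.

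Transcripts of the translation machinery moved little. Of 79 cytosolic ribosomal protein genes 9 rose and 0 fell, but adjusted over the list alone 1 rose, after quantile normalization 1 rose and 7 fell, and in the first and second library set 19 and 2 rose and 1 and 7 fell. RPL4 was 0.19 (SE 0.033) higher. Of 17 other genes with a terminal oligopyrimidine tract, 7 rose and 2 fell, and after quantile normalization 1 rose and 4 fell; EEF2 had a log2 fold change of 0.26 (SE 0.046, adjusted p = 0.000274), and 0.07 after quantile normalization (adjusted p = 0.249). Neither list was called (camera adjusted p = 0.339 and 0.277). Of 40 genes of ribosome biogenesis and MYC 16 rose, with MYC at 1.08 and ODC1, the rate-limiting enzyme of polyamine synthesis, at 0.89 (SE 0.047), and 8 fell (camera adjusted p = 0.242).

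Targets of the hypoxia-inducible factors divided. Of 26 tested, 12 rose and 8 fell (camera adjusted p = 0.277). EGLN3, the angiogenic factor VEGFA (-1.11), ADM (-0.89) and the lipid droplet gene PLIN2 (-0.81) fell, whereas ANGPTL4 (1.54), EDN1 (1.32) and ANKRD37 (1.24) rose. Of 28 genes of glycolysis and the pentose phosphate pathway 7 rose and 10 fell, and after quantile normalization 3 rose and 16 fell (camera adjusted p = 0.660). PFKFB3, an activator of glycolysis, fell from 5076 ± 326 to 2996 ± 108 units (-0.76, SE 0.044).

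Of 17 interferon-stimulated genes 6 rose and 9 fell (camera adjusted p = 0.443). IRF1 rose by 1.18 (SE 0.038) and DDX58 by 0.95, while IFI44L fell by 1.55 on the log2 scale and IFIT1 by 1.37. Of 14 targets of p53 6 rose, PLK3 by 2.08 (SE 0.066) and FAS by 1.07, and 2 fell, while CDKN1A (-0.04, adjusted p = 0.687) and MDM2 (0.01, adjusted p = 0.933) did not pass (camera adjusted p = 0.0891). Of 23 genes of nucleotide and folate synthesis 11 rose and 4 fell, but after thinning 6 rose and 5 fell and after quantile normalization 9 and 7, and SHMT1 was lowest (-0.67, SE 0.060; camera adjusted p = 0.339). Of 32 proteasome genes 3 rose, with their regulator NFE2L1 at 0.35 (SE 0.037), and 7 fell (camera adjusted p = 0.137). After quantile normalization and after thinning 2 rose and 18 fell, and the proteasome list was called (camera adjusted p = 0.0174 and 0.0327), but with an estimated correlation, without these changes, it had an adjusted p = 0.756, and 3 fell in the first library set and 10 in the second. Of 13 heat shock genes 8 fell, led by CHORDC1 (-0.83, SE 0.061), and 0 rose. That list stood at camera adjusted p = 0.0527 and passed within the first set (0.0214) and the second (0.0306), but not with an estimated correlation (adjusted p = 0.502).

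Among 11 markers of renal carcinoma 5 rose and 5 fell. CDH6 fell by 0.92 on the log2 scale and the cadherin CDH2 rose by 0.76 (camera adjusted p = 0.995). Of 29 markers of other cell types 4 were tested. EPCAM, at 55.2 ± 2.63 and 67.5 ± 3.42 units, had a log2 fold change of 0.29 (SE 0.075, adjusted p = 0.00499), a call lost within the second set (0.207) and after thinning to equal depth (0.233). Thinning was followed by a new scaling to the upper quartile, and the median log2 fold change over all genes was then -0.050, against -0.008 before. CD68 (-0.07), COL1A1 (-0.27) and SYP (-0.28) did not pass. Of 9 histone genes, of a class whose transcripts mostly lack poly(A) tails, 3 fell, HIST1H2AC by 0.54 on the log2 scale, and 0 rose (camera adjusted p = 0.277). Of 13 mitochondrially encoded genes in a fixed list, 0 were found in the authors' table under the names searched, so they could not be tested.

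In all, camera with the preset correlation called 12 of 28 lists, 6 higher and 6 lower, and with an estimated correlation 1, NF-kappaB and cytokines. At least 12 lists were called in 36 of 100 splits of the 11 samples, the real one included, whereas no other split drawn called a gene. The number of called lists thus does not set the real split apart. The other splits are not free of treatment, since the one with the most lists (16) had 3 everolimus libraries in the group taken as treated. They cannot tell chance from a part of the treatment difference. The exact permutation test of each list's mean, chosen after the data were seen, passed for 17 of 28 lists, 11 of the 12 called by camera among them and not oxidative phosphorylation (adjusted p = 0.124), with 0.00216 the smallest p it can give.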

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

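The tests of an interferon response, of the sign of genes called within 1 library set and of fractional reads among genes that differ at least 1.5-fold between the library sets were chosen only after the results they bear on were seen, as was the division into library sets itself.

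Among the values of the 50 named genes and the depth of the libraries, 4 of 102 groups held a library far from the rest of its group, and chance gives about 1 in 20. AARS in control 6 was lowest, at log2 12.04 with the nearest control at 12.13 (gap over range 0.771). FKBP1A in control 4 was lowest, at 11.57 against 11.67 (0.652). GADD45A in control 5 was highest, at 8.91 against 8.64 (0.638). IRF1 in everolimus 4 was lowest, at 10.36 against 10.47 (0.75).

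The number of changed genes was weighed against 4 explanations. Of 100 splits of the samples (from 462) only the real 1 gave as many genes, whether changed (6997), higher (3528), lower (3469) or changed at least 1.5-fold (1500). The highest count of any other drawn split was 0, which argues against a random labelling of these samples as the source. The other splits mix treated and control libraries, which widens the spread within their groups. Chance differences between cultures could not be tested, since the replicates may be technical. The split by library set, which was not drawn, gave 218 genes. For the number of called lists chance is not excluded, since 36 of 100 splits called at least 12 and the highest other called 16. The splits cannot decide this, because the others can carry a part of the treatment difference. Thinning every library to the depth of the shallowest gave 6647 genes (2755 higher, 3892 lower), 6038 of them among the 6997. At least 97.4% of the genes called in either library set had the same sign in the other. These values argue against depth and library set as the source. The smaller count under centring or quantile normalization was 7159, which argues against the choice among these scalings as the source of the count. The share of higher calls did move, from 50.4% to 44.6% after quantile normalization and 41.4% after thinning. Each of these scalings brings the libraries to a common level, so a change of total RNA per cell could not be seen. A response of the cells to the compound stays as the hypothesis.

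The rise of the NF-kappaB and cytokine list was weighed in the same way. After thinning its median log2 fold change was 2.43, and the smaller of its medians within the library sets was 2.47 over the 19 members tested (1.94 over the 15 kept by the filter within the second set, 2.05 over 14 in the first), which argues against depth and library set. Leukocytes in the treated cultures would bring their own transcripts, but the summed level of 7 leukocyte markers moved from 389.6 to 370.1 units, -0.256% of the rise of IL8, and without CD68, which made up most of that sum in both groups, the other 6 moved from 4.23 to 2.87 units with at most 10 reads for any of them in any library. An interferon response was not decided, because the interferon-stimulated genes had a median of -0.23 but went both ways (6 higher, 9 lower, SD of their log2 fold changes 0.77). Another action of the compound than on mTOR may contribute and cannot be told apart from inhibition of mTOR, because the labels give 1 dose of 1 compound.

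The division of the libraries was weighed last. Between the sets 500 genes differed by limma, 218 higher and 282 lower in the second, led by genes with near-identical copies such as PGAM4 (-3.80), HSPA1A (2.22), HSPA1B (-1.39) and RPL21 (-8.43), second minus first. Among genes of at most 2000 reads in every library, the 5574 with whole reads in all libraries differed at 0.25 times the rate of the other 1366 (2.5% against 9.7%), which lay at the bound set in advance and leaves open whether shared reads account for all of the difference. Of the 146 genes up to this limit that differed at least 1.5-fold (187 without it), 59.6% held fractional reads in some library. Of the others 18.8% did (exact Fisher test, p = 9.22e-27, which takes genes as independent). A different division of shared reads stays as a candidate source of the large differences. The sets were themselves divided by their share of whole low values, so a link with fractional reads is partly built in. These tests therefore cannot decide the source. Removing each library's trend with GC content and transcript length left 417 genes where 417 had differed before, 313 of them the same, against those trends as the whole cause, although the difference between the sets correlated with GC content across genes (Spearman 0.26, and 0.05 with length), so a part from GC content stays open, and no biological explanation was tested because the labels name no group that follows the sets.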

How the results depend on the processing

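The library set as a covariate, each set alone, thinning, voom weights, camera with an estimated correlation and the exact permutation test were chosen only after the data were seen. No called list or named gene changed its direction under an alternative run here. Over the alternatives fixed beforehand, leaving aside samples left out, 44 counts stayed within 1.5-fold of their main value and 1 did not. Of the gene and list results, 445 and 246 stayed on their side of the threshold, and 2 and 5 did not. The count of changed genes lay between 5075 (stricter filter, with 8552 genes tested) and 7444 (sample weights), and between 6397 and 7083 with each sample left out. Genes changed at least 1.5-fold fell to 693 under the stricter filter, which tests fewer genes. The share of higher calls was 50.4%, 44.6% after quantile normalization and 41.4% after thinning. Camera with an estimated correlation called 1 list, with or without the library set as a covariate. Without it the lost lists had adjusted p-values of 0.161 (cholesterol, fatty acid, G2/M, chaperones, immediate early, ERK), 0.170 (YAP), 0.253 (ATF4), 0.279 (NRF2), 0.502 (tRNA synthetases) and 0.824 (oxidative phosphorylation), and with it 0.170 (immediate early), 0.181 (cholesterol, fatty acid, G2/M, chaperones, ERK, YAP), 0.345, 0.351, 0.531 and 0.823. Estimating the correlation from 11 samples allows for more shared spread than the preset value. Oxidative phosphorylation had 0.645 within the first set and 0.005 to 0.150 with each sample left out, lost without control 3 (0.0548) and everolimus 4 (0.150), and the cause was not tested. Among named genes MTOR, EEF2 and EPCAM lost their calls under some alternatives, and the heat shock, proteasome, p53 and ribosomal protein lists, not called otherwise, passed under some. Replicate numbers were not treated as pairs. Deviations of same-numbered samples correlated at 0.60, 0.42, -0.51, 0.34 and 0.35, and 1 of 5 everolimus samples correlated best with its own number. Any everolimus and control library of the same set correlated at 0.32 to 0.61, and those of different sets at -0.61 to -0.27. These correlations thus follow the library set and cannot show whether the numbers are pairs. With the number as a block over 10 samples 6244 genes were called, 6115 of them among the 6997, and 13 lists, and MTOR had an adjusted p of 0.0823. Replicates within a group differed by a chi-square of 3.85 to 20.8 per gene, beyond sampling noise, so averaging near-identical samples was not run. The range was 3.85 to 10.7 within a library set and 10.7 to 20.8 across sets. It does not show that the replicates were separate cultures. Depth limits genes near the floor of 3 reads (0.92 to 3.15 units).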

Other observations

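The test of retinoid-responsive genes and the choice of genes in this part followed after the values of the largest changes had been seen, while the bounds of that test were set before the tested genes were looked up.

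Some genes outside the fixed lists changed by large amounts. TNF was at 1.94 ± 1.02 units in the controls (0 to 6 reads) and 187 ± 5.16 with everolimus. PTX3, a secreted pentraxin, rose from 29.1 ± 10.3 to 953 ± 80.1 units, and LTB, lymphotoxin beta, from 0.309 ± 0.484 to 26.7 ± 4.79. TRAF1 and IRAK2, adaptors of TNF and interleukin-1 family receptors, rose 12.1-fold and 11.3-fold, the survival gene BCL2A1 from 2.11 ± 1.29 to 62.9 ± 6.13 units, and the transcription factor MAFF 12.0-fold. G0S2, an inhibitor of lipolysis, rose from 90.4 ± 17.4 to 1434 ± 63.8 units. On the other side, ARTN, a neurotrophic ligand, fell from 225.6 ± 26.8 to 35.6 ± 6.01 units, S1PR1, a receptor for sphingosine-1-phosphate, from 503.5 ± 19.6 to 88.5 ± 7.92, and the interferon-induced RSAD2 from 134.9 ± 9.93 to 30.8 ± 7.02. Each of these passed the limma threshold, with no overlap between groups.

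DHRS3, which reduces retinaldehyde, fell from 790.4 ± 98.6 to 114.5 ± 28.8 units, and CYP26B1, which degrades retinoic acid, from 23.6 ± 4.72 to 3.13 ± 1.08. Both are induced by retinoic acid, so lower retinoic acid signalling was tested as a hypothesis on 9 other retinoid-responsive genes. Their median log2 fold change was -0.45, between the bounds of -0.5 and -0.2 set for and against it, so the hypothesis may hold but was not decided. Among them RARA (-0.97), NRIP1 (-0.64), HOXA5 (-0.49), RARRES3 (-0.45) and CRABP2 (-0.41) fell, TGM2 rose (1.19), and STRA6 (-0.17, adjusted p = 0.331) and RARRES1 (0.11, adjusted p = 0.433) did not pass.

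Of the 26 entries named by numbers, the entry named 42798 rose 7.01-fold, from 9.57 ± 4.56 to 64.6 ± 7.95 units, with a log2 fold change of 3.21 in the first and 2.41 in the second library set. Which gene it stands for was not determined. Gene families taken from shared symbol stems gave no further theme. Of 50 families, 0 passed camera with the library set as a covariate and 9 had an unadjusted p under 0.05. The lowest adjusted p was 0.0533, for 20 splicing factors with the stem SFRS, 12 of which fell and 0 rose, with a median of -0.15 in each library set.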
